A study of Mus musculus with 6 samples.

How the data were processed

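RNA was measured in hearts of 6 mice on Affymetrix Mouse Gene 1.0 ST arrays, 1 heart per array, in 2 groups of 3: wild type and A2a-R transgenic littermates, all after transverse aortic constriction. Per the labels' protocols, total RNA was isolated with Trizol and 100 ng was turned into biotin-labelled single-stranded cDNA with the array maker's terminal labelling kit. The deposited values are on the log2 scale; per the submitters' processing notes the authors used RMA, which corrects background, quantile-normalises arrays and summarises probes, and the Partek software. Versions and the settings of these steps are not given in the sources used here, nor is a genome build. The value table holds 28853 rows with 2 decimals and values between 2.51 and 14.69. Because RMA forces similar distributions on the arrays, a global shift in RNA content per heart is not visible in these values, and changes of dim and of very bright transcripts are compressed.

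Genes were named from the platform annotation dated 2016 that accompanied the values. Exactly 1 gene symbol was given for 21789 rows, several for 1621 and none for 5443. The symbols of 21698 rows were looked up by Entrez identifier in RefSeq annotation of assembly GRCm38.p6, which changed 0 of them. Only rows with exactly 1 symbol were tested; they cover 19938 genes, 999 of them with more than 1 row. For gene-level statements the row with the highest mean over the 6 arrays was used. The RefSeq table was also used for the order of genes along chromosomes, and no coordinates were taken from it.

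The comparison was transgenic minus wild type. Each row was fitted with limma (lmFit and eBayes, default prior, no covariate) on the deposited values as they stand, and p-values were adjusted by Benjamini-Hochberg over the tested rows with a threshold of 0.05. The design text gives 3 mice per group, so the p-values set the group difference against the spread between animals within groups. That spread is moderated by a prior drawn from all tested rows (4.1 prior degrees of freedom). The titles number the hearts of each group 1 to 3, while their descriptions number the wild-type hearts 3 to 5 and the transgenic hearts 1 to 3, and nothing in the labels ties equal numbers to a shared litter or day, so no pairing was used. No array equalled another over all rows; 494 to 785 of the tested rows held the same value in both arrays of a pair. Errors are SD over the 3 hearts of a group or the moderated SE of the log2 difference, with 95% intervals from the same fit. The arrays' number limits the precision: the median SE of a log2 change was 0.0731.

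Before the data were examined, 32 lists of pathway genes and cell type markers were fixed, with 659 genes, of which 594 had a row of their own; 31 lists had the required 5 measured genes, and the red blood cell list, with 4, was not tested. The members measured there differed by -0.77 (Alas2, which fell), -0.22 (Fech), -0.02 (Slc4a1) and 0.06 (Bpgm) on the log2 scale. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 31 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, were run beside it. Counts of list members are given over all tested rows and adjusted over the list alone. A rule fixed in advance chose the genes to name: the adenosine receptors, the 10 largest rises and 10 largest falls among called genes with non-overlapping groups, 8 genes of cardiac load and fibrosis (Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1 and Col3a1), and up to 4 members with the smallest p of each list that was called or held a called member. Lcn2, Xirp2, Cd68, Cd163, Itgam, Tlr4, Tnf, Icam1, Vcam1, Sele, Tagln, Myh11, Nt5e, the members of the red blood cell list and the genes of the closing part were named outside that rule, after their values had been seen.

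The same code was tested on simulated values drawn from the 21789 real rows with 200 rows changed, 3 arrays against 3. It recovered 92% of rows changed by 0.5 and 99% of rows changed by 1 on the log2 scale, and 4.98% of its calls were unchanged rows. The noise was normal, with each row's moderated variance from the real fit. That variance is drawn toward a common value, so recovery in the real rows may be lower. In the simulated lists, 16 of 16 shifted by 0.2 were called, and 0 of the unshifted lists. These lists held random genes with independent noise, so they cannot show how often correlated genes give false list calls. In the 5 real lists that camera called, the estimated correlation ran from -0.03 (angiogenesis) to 0.44 (hypertrophy), against the preset 0.01. Alternatives fixed in advance were the replicate number as a block, a further quantile normalization, centring arrays on their medians, leaving out the dimmest 40% of rows, a trended and robust variance prior, array weights, other thresholds, all rows of the table, other ways to reduce rows to genes, other list tests, and leaving out each array in turn. Computations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.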

Results

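Gene expression was profiled in whole hearts of 6 male mice of the FVB strain, an inbred albino line, after transverse aortic constriction, a surgical narrowing of the aortic arch that loads the left ventricle with pressure. Surgery was done at 8 weeks of age and hearts were collected 14 weeks later, as far as the labels say. In 3 of the mice the adenosine A2a receptor, a G protein-coupled receptor that raises cyclic AMP, was over-expressed in the heart from an inducible transgene, and 3 littermates were wild type. Each heart was measured on 1 array, so each group had n = 3 animals and the number of arrays limits the precision. The mean log2 value of an array lay between 7.03 and 7.06. The spread differed by genotype: the SD over all rows was 2.083 to 2.099 in wild-type and 2.052 to 2.066 in transgenic arrays. The upper quartile was 8.42 to 8.44 in wild-type arrays and 8.39 in each transgenic array. Whether this slightly narrower range comes from the hearts or from the processing was not tested, and it may bear on small changes of bright genes. Arrays of the same genotype correlated at r = 0.9958 to 0.9973 across 21789 tested rows and arrays of different genotype at r = 0.9926 to 0.9957, where rows are not independent replicates. The single comparison of the design asked which transcripts differ between pressure-loaded transgenic and wild-type hearts. Unoperated hearts were not analysed here, so no value below separates the transgene from its interaction with the surgery.

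Among the genes that changed, Acta1 and Nppa were lower and the chemokine genes Cxcl13 and Ccl8 higher in the transgenic hearts. Acta1, the skeletal alpha-actin that is re-expressed in the loaded ventricle, fell from a log2 value of 13.27 ± 0.17 to 11.77 ± 0.58 (SD, n = 3 each), and Nppa, which encodes atrial natriuretic peptide, fell from 13.60 ± 0.38 to 12.42 ± 0.31. The call of Nppa was lost without any 1 array (limma adjusted p 0.0636 to 0.124) and that of Acta1 without wild-type replicate 1, 2 or 3 or transgenic replicate 1 (up to 0.129). Cxcl13, a B cell-attracting chemokine, rose from 6.36 ± 0.28 to 8.23 ± 0.30, and Ccl8, a monocyte-attracting chemokine, rose from 5.86 ± 0.37 to 7.56 ± 0.12. Col1a1, the main chain of fibrillar collagen, had the same mean of 9.39 in both groups, with a 95% interval for the log2 difference of -0.26 to 0.26.

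In all, 209 rows changed at an adjusted p below 0.05 in limma, 113 of them higher and 96 lower in the transgenic hearts. They belonged to 203 genes, of which 109 rose and 94 fell, where any passing row counted. Of these genes 13 had several rows, and in only 3 of the 13 did all rows pass in the same direction. The change was at least 1.5-fold in 103 rows, with 63 higher and 40 lower, and at least 2-fold in 31. The values of the 3 transgenic hearts did not overlap those of the 3 wild-type hearts in any of the 209 rows, which selection by p-value nearly ensures. Over all tested rows the groups did not overlap in 20.3%, where chance gives 10%. At an unadjusted p below 0.01 and a change of at least 1.5-fold there were 157 rows, 102 higher and 55 lower. The count of changed rows went up to 493 without the dimmest 40% of rows and to 579 with a trended and robust variance prior. In both the balance turned, with 184 higher and 309 lower in the first and 240 higher and 339 lower in the second. It also turned with arrays centred on their medians (129 higher, 147 lower) and at an adjusted p below 0.10 (230 higher, 246 lower). It was 124, 84 and 92 without wild-type replicates 1, 2 and 3, and 147, 116 and 121 without transgenic replicates 1, 2 and 3.

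Among the 10 genes with the largest rise, Cxcl13 was 3.67-fold higher (log2 change 1.88 ± 0.17 SE, limma adjusted p = 0.0042) and Ccl8 was 3.24-fold higher (1.70 ± 0.17, adjusted p = 0.00486). Cdo1, the cysteine dioxygenase that starts taurine synthesis, rose 3.12-fold and Phkg1, a catalytic subunit of phosphorylase kinase, rose 2.61-fold. Serpina3n, a secreted protease inhibitor of the acute phase, rose from 10.46 ± 0.13 to 11.81 ± 0.01 (SD, n = 3), with a limma adjusted p of 0.000568. Pla2g5, a secreted phospholipase A2, rose 2.49-fold and Tmprss13, a membrane serine protease, 2.45-fold. Rtl3, a gene derived from a retrotransposon, rose 2.85-fold. Cfap61, a cilium protein, rose 2.77-fold and Fam122b rose by 1.32 ± 0.13 (SE) on the log2 scale. All of these 10 calls held when any 1 array was left out.

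Among the 10 genes with the largest fall, Lgi1, which encodes a secreted leucine-rich repeat protein, fell by 1.70 ± 0.21 (SE) and Fgf6, a fibroblast growth factor of striated muscle, fell by 1.67 ± 0.08 on the log2 scale (limma adjusted p = 0.0112 and 0.000568). Gnb3, a G protein beta subunit, fell by 1.59 ± 0.17, B3galt2, a galactosyltransferase, fell by 1.43 ± 0.14 and Scgb1c1, a secretoglobin, fell by 1.42 ± 0.15. Acta1 was 2.83-fold lower, with a 95% interval of the log2 change from -2.08 to -0.93 (limma adjusted p = 0.0375), and Nppa fell by 1.18 ± 0.21 (limma adjusted p = 0.0456). Bex1 fell by 1.09 ± 0.12, the T-box factor Tbx15 fell by 0.99 ± 0.15 and Syndig1, a membrane protein of synapses, fell by 0.98 ± 0.16. The calls of Acta1 and Nppa were fragile: a trended and robust variance prior gave limma adjusted p of 0.118 and 0.114. The call of Nppa was lost without any 1 of the 6 arrays (0.0636 to 0.124), and that of Acta1 without wild-type replicate 1, 2 or 3 or transgenic replicate 1 (up to 0.129). Lgi1 lost the call without wild-type replicate 2 (0.0636), Tbx15 without wild-type replicate 1, 2 or 3 or transgenic replicate 1 (up to 0.109), and Syndig1 without any array but wild-type replicate 1 (up to 0.118).

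**Figure D1:**
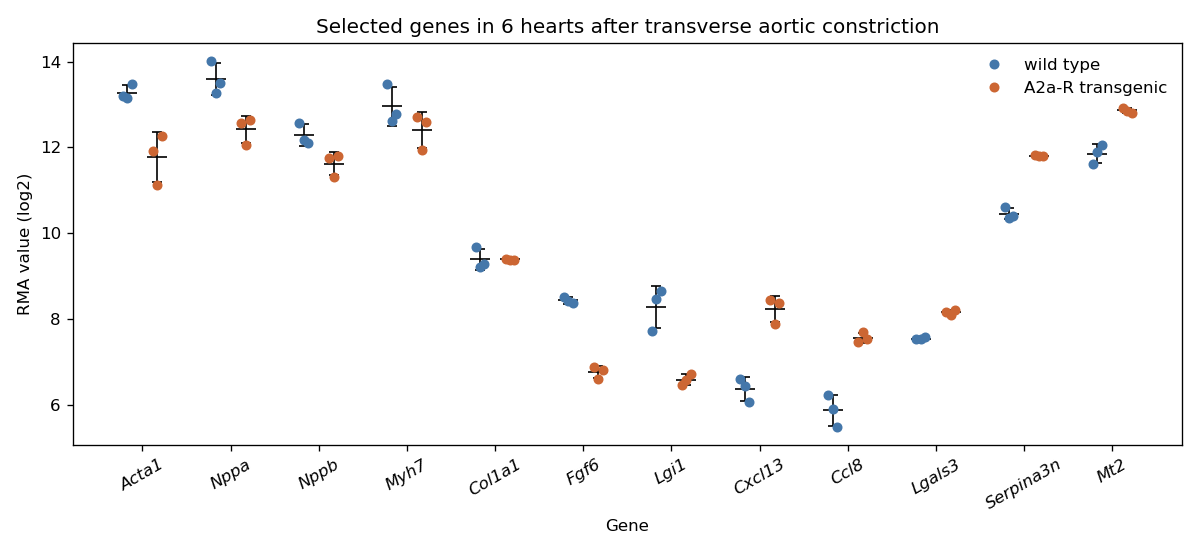
RMA values on the log2 scale (vertical axis) of 12 genes (horizontal axis) in the 3 wild-type and the 3 A2a-R transgenic hearts; each dot is 1 heart, the dash is the group mean and the bar is 1 SD on either side. Fgf6 has means of 8.43 and 6.76 and Serpina3n of 10.46 and 11.81 in wild-type and transgenic hearts, whereas both means of Col1a1 are 9.39.

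The hypertrophy and fetal gene program, the set of genes that a pressure-loaded ventricle switches on, lay lower in the transgenic hearts. Of its 19 measured genes, 17 were lower; Acta1 and Nppa fell, Uchl1, a ubiquitin hydrolase, rose by 0.44 ± 0.08, and 16 did not pass. When p-values were adjusted over the list alone, 9 genes were lower and 1 higher. The median log2 change was -0.30 with quartiles of -0.55 and -0.14 (camera adjusted p = 8.8e-05, from limma); the adjusted p was 0.602 with an estimated correlation. Nppb, which encodes brain natriuretic peptide, differed by -0.66 ± 0.16 (SE, limma adjusted p = 0.117), the sarcomere-associated Xirp2 by -0.55 ± 0.12 (0.0987), Enah, a regulator of actin filaments, by -0.40 ± 0.09 (0.0966), and Myh7, the slow myosin heavy chain, by -0.55 ± 0.26 (0.368). The list's mean stood 0.36 above its 6-array mean in wild-type replicate 1 and at -0.37 from it in transgenic replicate 2, against deviations of -0.0025 and 0.19 in the other two wild-type hearts and of -0.09 in both other transgenic hearts. The 20 cAMP-responsive immediate early genes, not called as a list (median -0.23, 15 lower, camera adjusted p = 0.196, from limma), also stood highest in wild-type replicate 1 (0.37) and lowest in transgenic replicate 2 (-0.44), with 0.29 in transgenic replicate 3.

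Of 19 sarcomere genes 14 were lower and none passed in limma, over all genes or adjusted over the list alone, although 6 had an unadjusted p below 0.05; their median was -0.06 (camera adjusted p = 0.126). Myh6, the fast myosin heavy chain, differed by -0.06 ± 0.06 (SE) and Atp2a2, the calcium pump of the sarcoplasmic reticulum, by 0.02 ± 0.06. Of 18 calcium handling genes, 0 passed in limma over all genes, 4 had an unadjusted p below 0.05, and 1 passed when adjusted over the list alone, the kinase Camk2d at -0.28 ± 0.05. Among 20 ion channel and gap junction genes, Kcnq1, which carries a slow repolarising potassium current, rose by 0.46 ± 0.08 (limma adjusted p = 0.0463) and 19 did not pass. There, 3 were higher and 2 lower adjusted over the list alone, among them Kcnj2 at 0.40 ± 0.07 and Kcnip2 at -0.38 ± 0.08. Pde3a, a phosphodiesterase that breaks down cyclic AMP, rose by 0.33 ± 0.06 (limma adjusted p = 0.0474), 1 of 22 genes of beta-adrenergic and cAMP signalling. Of the 22, 3 were higher adjusted over the list alone, with Pde3b at 0.34 ± 0.08 and Pde4d at 0.29 ± 0.08. The calls of Kcnq1 and Pde3a did not survive the loss of any 1 array, with limma adjusted p of 0.0663 to 0.162 and 0.0943 to 0.151, nor centring the arrays on their medians (0.0584 and 0.0703).

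Macrophage and monocyte markers were higher in the transgenic hearts. Of 23 measured markers, 21 were higher; Lgals3, the lectin galectin-3, rose by 0.61 ± 0.06 (SE) and the lysozyme gene Lyz1 by 0.53 ± 0.08 (limma adjusted p = 0.00423 and 0.0272), and 21 did not pass. Adjusted over the list alone, 11 were higher, among them the protease Ctss at 0.36 ± 0.06 and the complement gene C1qb at 0.42 ± 0.08. The median was 0.20 with quartiles of 0.14 and 0.39 (camera adjusted p = 2.04e-11, from limma); the adjusted p was 0.467 with an estimated correlation. The list's mean deviated from its 6-array mean by -0.09, -0.09 and -0.19 in the wild-type hearts and in the transgenic hearts by 0.10, 0.17 and 0.11. Cd68, a lysosomal protein of macrophages, was at 0.62 ± 0.12, the scavenger receptor Cd163 at 0.00 ± 0.07 and the integrin Itgam at -0.06 ± 0.08. The call of Lyz1 was lost without any 1 array except wild-type replicate 1, with a limma adjusted p of up to 0.12. The call of Uchl1 in the hypertrophy list was lost in the same 5 fits (up to 0.174).

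The list of inflammatory cytokines and adhesion molecules was the second one called in the upward direction. Of 28 measured, 18 were higher and 10 lower; 5 rose and 23 did not pass. Those that rose were Cxcl13, Ccl8, the chemokines Ccl6 at 0.62 ± 0.06 and Ccl9 at 0.59 ± 0.09 (SE), and Lcn2, the iron-sequestering lipocalin-2, at 0.66 ± 0.12 with a limma adjusted p of 0.0474. Of the 28, 7 were higher adjusted over the list alone and 1 lower, the receptor Tlr4 at -0.28 ± 0.08. The cytokine Tnf, which did not pass, was at -0.46 ± 0.20. The adhesion genes Icam1, Vcam1 and Sele did not pass either, at 0.06, 0.05 and -0.05. The median was 0.07 with quartiles of -0.16 and 0.29 (camera adjusted p = 0.0175, from limma); the adjusted p was 0.602 with an estimated correlation, and 0.0616 by the preset correlation without transgenic replicate 3. The calls of Ccl9 and Lcn2 were lost without any 1 array except wild-type replicate 3 (limma adjusted p up to 0.116 and 0.153).

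Angiogenesis and vascular regulators and the heat shock chaperones lay slightly lower. Of 25 vascular genes 20 were lower and 0 passed in limma over all genes, while 9 had an unadjusted p below 0.05. Adjusted over the list alone, 3 were lower and 1 higher: the growth factors Vegfa at -0.28 ± 0.05 and Vegfc at -0.36 ± 0.07 (SE), Hif1a, the oxygen-regulated transcription factor, at -0.35 ± 0.09, and Agt, the angiotensin precursor, at 0.30 ± 0.06. Their median was -0.11 (camera adjusted p = 0.0277, from limma); the adjusted p was 0.489 with an estimated correlation. Of 12 chaperone genes 10 were lower, 0 passed in limma over all genes or adjusted over the list alone, and 4 had an unadjusted p below 0.05, such as Hsp90aa1 at -0.21 ± 0.05 and the co-chaperone Bag3 at -0.19 ± 0.05. Their median was -0.13 (camera adjusted p = 0.0287, from limma); the adjusted p was 0.602 with an estimated correlation. Without wild-type replicate 2 or transgenic replicate 1 the vascular list had a camera adjusted p of 0.0795 and 0.076, and the chaperones had 0.0697 and 0.129, and 0.111 without wild-type replicate 3.

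No shift was called for extracellular matrix and fibrosis genes, whose median was -0.06 over 36 genes (camera adjusted p = 0.328, from limma). Over all genes 0 passed in limma, against 12 at an unadjusted p below 0.05. In this list 4 were higher and 4 lower adjusted over the list alone: among them Timp1, an inhibitor of metalloproteinases, was at 0.62 ± 0.12 (SE), Col14a1 at 0.62 ± 0.12, the matrix glycoprotein Tnc at 0.47 ± 0.10 and Thbs1, thrombospondin-1, at -0.58 ± 0.13. Col3a1 differed by 0.15 ± 0.13. The list's mean stood 0.32 above its 6-array mean in wild-type replicate 1 and between -0.12 and -0.0044 in the remaining 5 hearts.

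Single members of other lists changed. Of 24 antioxidant genes, 2 rose and 22 did not pass: the metallothioneins Mt1 at 0.75 ± 0.07 and Mt2 at 1.01 ± 0.11 (SE, limma adjusted p = 0.00486 and 0.0056), also the count adjusted over the list alone. Asns, asparagine synthetase, rose by 0.59 ± 0.07, 1 of 22 genes of the unfolded protein and amino acid stress response, where 2 were higher adjusted over the list alone, the second being Mthfd2 at 0.45 ± 0.10. The apoptosis regulator Bcl2 fell by 0.79 ± 0.13, 1 of 20 genes of apoptosis and autophagy; adjusted over the list alone 1 was lower and 1 higher, the latter Map1lc3a at 0.43 ± 0.09. Cyclin D1, Ccnd1, fell by 0.36 ± 0.05, 1 of 25 cell cycle genes and also 1 adjusted over the list alone. Of 18 genes of glucose uptake and glycolysis 0 passed in limma over all genes and 3 had an unadjusted p below 0.05; 1 was lower when adjusted over the list alone, Pfkfb2 at -0.30 ± 0.06. The limma adjusted p of Asns was 0.0504 without wild-type replicate 3. The call of Bcl2 was lost without wild-type replicate 2 or transgenic replicate 1, 2 or 3 (up to 0.117), and that of Ccnd1 without any 1 array (up to 0.112).

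The medians of the other cell type lists lay between -0.08 and 0.05. Acta2, the smooth muscle actin, rose by 0.73 ± 0.09 (SE, limma adjusted p = 0.0106), but it was the single call among 15 smooth muscle and pericyte markers, also adjusted over the list alone, and the list's median was 0.04; Tagln was at 0.08 ± 0.06 and Myh11 at -0.06 ± 0.07. Medians were 0.01 for 18 fibroblast markers, -0.06 for 19 endothelial markers and 0.05 for 19 T, NK and B cell markers, with camera adjusted p of 0.626, 0.538 and 0.185 from limma. Il7r, the interleukin-7 receptor, rose by 0.57 ± 0.07 in the last of these, where 1 was higher and 1 lower adjusted over the list alone, the latter Cd79a at -0.35 ± 0.09. Of 14 white and brown fat markers 10 were lower, with a median of -0.08 (camera adjusted p = 0.126, from limma; fry adjusted p = 0.028); 0 passed in limma over all genes or adjusted over the list alone, and 4 had an unadjusted p below 0.05. For 16 neutrophil and mast cell markers the median was -0.04, the mean 0.0004 and the test's direction up (camera adjusted p = 0.659). For 16 circadian clock genes the median was -0.03, the mean 0.02 and the direction up (0.804). For 14 atrial markers the median was -0.04, the mean -0.06 and the direction up (0.729): Nppa fell, and Tbx5, a transcription factor, was at 0.34 ± 0.08, the call adjusted over the list alone in the upward direction. Acta1 was the single call among 16 skeletal muscle markers, whose median was 0.02, mean -0.09 and direction up (0.729), and Uchl1 among 12 nerve and Schwann cell markers, over all genes and adjusted over the list alone. Acta2 had a limma adjusted p of up to 0.0594 without 1 array (lost without wild-type replicate 1 or 3), and Il7r one of 0.05 without wild-type replicate 3.

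**Figure D2:**
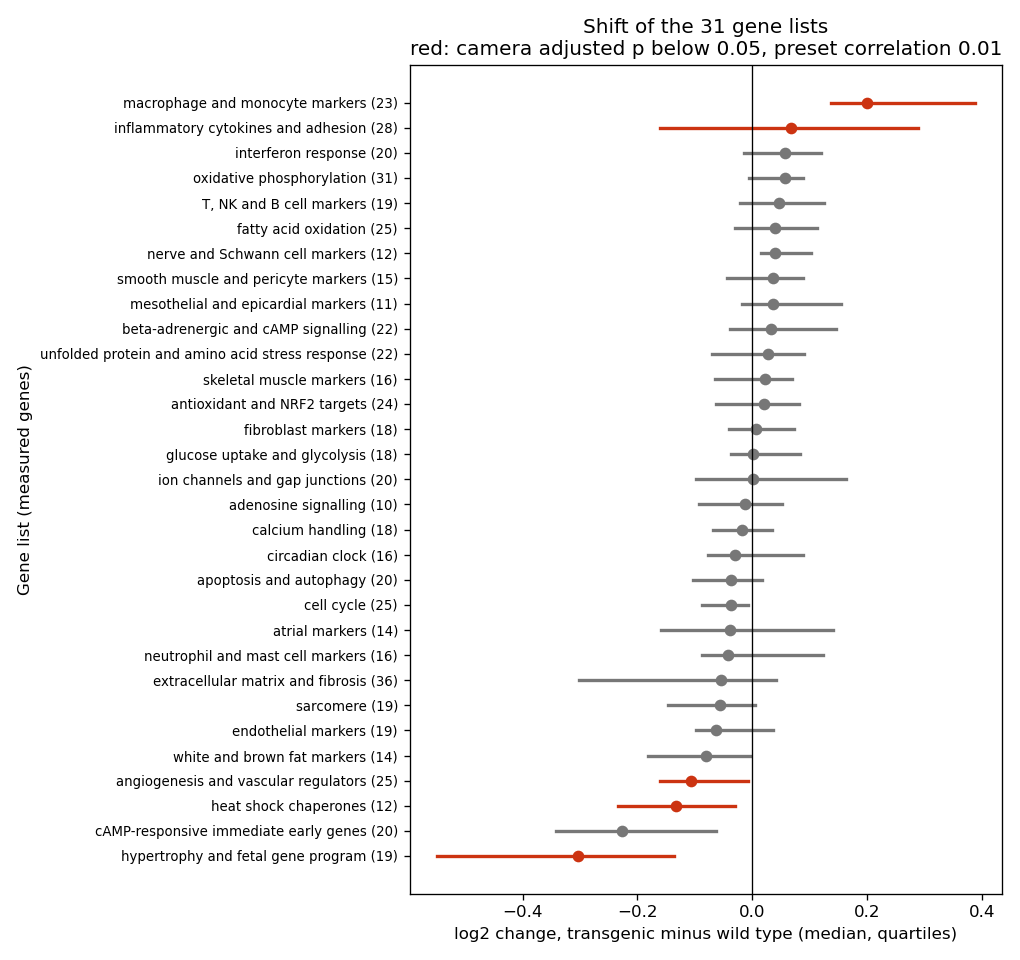
Change in log2 value, transgenic minus wild type (horizontal axis), for the 31 gene lists with at least 5 measured genes (vertical axis, number of genes in brackets); dots are medians and bars span the quartiles over genes, and red marks a camera adjusted p below 0.05 with the preset correlation. The macrophage and monocyte list has the highest median at 0.20 and the hypertrophy and fetal gene list the lowest at -0.30.

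Altogether 5 of 31 lists were called by camera with the preset correlation of 0.01, and 26 were not, with adjusted p from 0.0676 to 0.804. Estimating the correlation within each list left 0 called in limma, with 2 at an unadjusted p below 0.05, while fry called 5. Of these, the macrophage and the vascular lists were also called by camera, and the antioxidant, the beta-adrenergic and cAMP, and the fat lists were not (fry adjusted p = 0.0275, 0.0348 and 0.028). Other splits of the 6 arrays into groups of 3 called 3 to 10 lists.

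The receptor named by the transgene could not be used as a check of the labels: Adora2a and the other 3 adenosine receptor genes were not analysed here. Of the 10 measured genes of adenosine signalling, 0 passed in limma over all genes or adjusted over the list alone and 1 had an unadjusted p below 0.05. That gene was Nt5e, the ectonucleotidase that forms adenosine, at -0.36 ± 0.10 (SE, limma adjusted p = 0.17), and the list's median was -0.01 (camera adjusted p = 0.682).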

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

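The tests of explanations in this part and in the last part were chosen after the patterns had been seen, except the counts over other splits of the arrays, and the criteria for a uniform share of macrophages and for a single heart were changed after their results had been seen. With 3 hearts per group no test for a heart far from the others was made. Rows of the table that carry no gene symbol or several were kept out of the report's comparison; of these 7064 rows, 51 changed in a limma fit over all 28853 rows at an adjusted p below 0.05, 43 higher and 8 lower in the transgenic hearts. They were 21 rows with no symbol and 30 with several, and are not named here.

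Of the 10 ways to split the 6 arrays into groups of 3, only 1, the genotypes themselves, gave as many as 209 changed rows in limma. The other 9 splits called 0, with 577 to 1820 rows at an unadjusted p below 0.05 against 3220. With 10 splits no share can fall under 0.05. For the number of called lists, 8 of the 10 splits gave 5 or more, with 5 for the genotypes and up to 10 for the split that sets wild-type replicate 1 and transgenic replicates 1 and 3 against the rest. Of the 9 other splits, 4 called the macrophage list and 4 the hypertrophy list. None gave the macrophage list an adjusted p as small as the genotypes did (2.04e-11, against 1.79e-05 at best), and 2 gave a smaller one for the hypertrophy list (8.8e-05 for the genotypes) and 2 for heat shock (0.0287).

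The lower hypertrophy and fetal genes were weighed against 3 technical readings. A single heart out of line stays open: the camera adjusted p of the list was at most 0.00159 without any 1 array, but 4 of the 9 other splits called the list too, so this test excludes nothing. More atrial tissue in the wild-type samples, the source of much Nppa, would lower the other atrial markers about as much as Nppa, and the 13 others had a median of -0.0133 with quartiles of -0.14 and 0.16, against an interval of -1.65 to -0.70 for Nppa. A lower share of cardiomyocytes would take the sarcomere genes along, and their median was -0.0567 with a lower quartile of -0.15. A weaker stress response in the transgenic hearts, which may also follow from a milder narrowing of the aorta in these 3 animals, stays open and was not tested.

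The higher macrophage markers were weighed against 2 readings. A lower share of cardiomyocytes would raise the markers of every other cell type alike, yet 52 pooled fibroblast, endothelial and smooth muscle markers had a median of -0.0117 with quartiles of -0.07 and 0.07. A uniformly larger share of macrophages would raise all their markers by one factor. The 95% interval held the list's median of 0.20 in 60% of the 20 brighter members (12), but among the 11 members above the list's median brightness a single change lay in the intervals of 9 (81.8%). Because values of dim transcripts are compressed to an extent not measured here, this reading stays open, as does a change in the kind or state of the macrophages, which was not tested.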

How the results depend on the processing

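All alternatives here were chosen before the data were examined, and the genes of the last part were picked after their values had been seen. With the replicate block, taken from the titles (the descriptions number the wild-type hearts otherwise), 97 rows changed (60 higher, 37 lower, 90 shared with the 209). The deviations of equally numbered arrays correlated across rows at 0.162, -0.006 and -0.115. Unequally numbered arrays of different genotype ranged from -0.216 to 0.239. These values cannot decide whether equal numbers share a litter or day, and the titles may not give the true pairs. Without the dimmest 40% of rows 493 changed (184 higher, 309 lower), with the trended and robust prior 579 (240 and 339), at an adjusted p below 0.10 476 (230 and 246) and with a change of at least 1.5-fold 103 (63 and 40). Centring arrays on their medians gave 276 (129 and 147). Fits without 1 array gave 84 to 147 changed rows, 56 to 102 higher and 28 to 53 lower, where fewer arrays were compared. A further quantile normalization, array weights, all rows of the table and 1 row per gene kept the counts within 1.5 times. They shared 193, 208, 157 and 198 rows with the 209. The fit on all rows called 208 (133 higher, 75 lower), so a similar count there hid a change of members.

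The number of lists called was 9 without the dimmest rows, 0 with an estimated correlation (2 at an unadjusted p below 0.05; 5 by fry) and 3 to 7 without 1 array. With an estimated correlation the adjusted p was 0.602 for the hypertrophy, inflammatory and heat shock lists, 0.489 for angiogenesis and 0.467 for macrophages. By fry it was 0.194 for hypertrophy, 0.0932 for inflammatory genes and 0.182 for heat shock. Angiogenesis and heat shock had 0.0968 and 0.11 after quantile normalization and 0.128 and 0.0867 without the dimmest rows. Without 1 array, adjusted p ranged from 0.0081 to 0.0616 for inflammatory genes, 0.0134 to 0.0795 for angiogenesis and 0.00128 to 0.129 for heat shock; the hypertrophy and macrophage lists had at most 0.00159 and 1.33e-07. The cause was not tested except where given.

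Over 95 genes named by the rule and 1126 pairs of gene and alternative, 991 kept the side of the threshold without a counted reversal. Of the rest, 73 lost the call, 59 gained it and 3 reversed. All 3 were Atp2a2, close to 0 throughout: -0.00628 with array weights and -0.0167 to 0.0333 without 1 array, with -0.00667 without transgenic replicate 2. Col1a1, with a main change of 0, had no direction to reverse and ran from -0.08 to 0.14 over the alternatives. Of 34 called genes, 24 kept the call in each alternative that used all arrays and 19 in each fit without 1 array. The alternatives for Adora2a were not run, as it was not analysed here. The signal over background was not measured, so a limit set by dim probes stays unknown.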

Other observations

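The genes and tests of this part were chosen after their values had been seen. Those of the first paragraphs, up to the X chromosome, were picked because they were called, so they speak for no wider group, and no list test stands behind them. Among those that rose were Retnla, a marker of alternatively activated macrophages, by 0.80 ± 0.11 (SE), Gpnmb by 0.68 ± 0.09, the macrophage elastase Mmp12 by 0.67 ± 0.09 and the complement component C4b by 0.92 ± 0.09, with limma adjusted p of 0.0155, 0.015, 0.0148 and 0.00486. Fcer1g, an adaptor of Fc receptors, rose by 0.49 ± 0.08 and Wfdc17 by 0.60 ± 0.08. Others that rose were the cystine transporter Slc7a11 by 0.80 ± 0.07, the cationic amino acid transporter Slc7a1 by 0.58 ± 0.07, Aass of lysine breakdown by 0.68 ± 0.07 and Hal of histidine breakdown by 0.45 ± 0.05 (limma adjusted p = 0.00286, 0.0126, 0.00486 and 0.0101). The fixed list of the unfolded protein and amino acid stress response was not called (camera adjusted p = 0.239, from limma). In the fits without 1 array C4b, Slc7a11 and Aass kept the call each time, and Fcer1g, Gpnmb, Retnla, Wfdc17, Mmp12, Slc7a1 and Hal lost it in 5, 4, 3, 3, 2, 2 and 2 of the 6, with adjusted p up to 0.138.

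Of the picked genes that fell, Hbegf, a heparin-binding ligand of the EGF receptor, fell by 0.92 ± 0.12 (SE), Etv5, a transcription factor of the ERK pathway, by 0.73 ± 0.11, Edn3, endothelin-3, by 0.84 ± 0.09, and Wif1, a secreted Wnt inhibitor, by 0.72 ± 0.09. Ddah1, which clears an inhibitor of nitric oxide synthase, fell by 0.88 ± 0.10. Tmod4, a cap of actin filaments, fell by 0.84 ± 0.09, Synpo2l by 0.50 ± 0.08 and Lmod3, a nucleator of actin filaments, by 0.38 ± 0.06, with limma adjusted p of 0.00694, 0.0278 and 0.0223. Mstn, which encodes myostatin, a brake on muscle growth, rose by 1.28 ± 0.19, Bmp2 rose by 0.89 ± 0.09, and the water channels went opposite ways, with Aqp4 up by 0.93 ± 0.06 and Aqp1, which fell, at -0.58 ± 0.07 (limma adjusted p = 0.0236, 0.00535, 0.00111 and 0.0106). The fixed sarcomere and skeletal muscle lists were not called (camera adjusted p = 0.126 and 0.729, from limma). Without 1 array the calls of Edn3, Ddah1, Tmod4, Bmp2 and Aqp4 held each time; those of Synpo2l, Lmod3, Etv5, Mstn, Wif1, Aqp1 and Hbegf were lost in 6, 5, 4, 4, 2, 2 and 1 of the 6, with adjusted p up to 0.108.

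Most of a run of neighbouring genes at the distal end of the X chromosome was higher in the transgenic hearts. In the gene order of assembly GRCm38.p6 it starts at Tlr8 and holds 11 measured genes up to the chromosome's end, of which 6 rose: Tlr8 2.08-fold, Tlr7 2.12-fold, Prps2 1.86-fold, Hccs 1.79-fold, Msl3 1.67-fold and Arhgap6 1.49-fold, each also without any 1 array (limma adjusted p up to 0.0479). Mid1 was at 0.55 ± 0.11 (SE, limma adjusted p = 0.0818), and G530011O06Rik, Frmpd4, 4933400A11Rik and Amelx were at 0.27, 0.21, 0.14 and -0.02. None of the 20 measured genes just before Tlr8 was called in limma, with 0 at an unadjusted p below 0.05, and their changes ran from -0.10 to 0.13. Among 7-gene windows over the genome the highest median, 0.74, lay here; off the X chromosome the highest was 0.59, on chromosome 11, and over 100 shuffles of gene order 0.467.

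An extra copy of the segment in the transgenic mice stays open. The 8 brighter genes of the run had a median of 0.79 and the 20 genes before it one of -0.01, but the limits of the run were set from the rise itself, so these values restate the pattern and do not test a copy. A larger number of macrophages, which express Tlr7 and Tlr8, was weighed on the 6 other brighter genes. Their median of 0.66 lay above the highest member of the macrophage list, 0.62, and 5 lay above its upper quartile, 0.39. The 95% intervals of Prps2, Hccs, Msl3, Arhgap6 and Mid1 started at 0.74, 0.70, 0.60, 0.41 and 0.28, above the list's median of 0.20. G530011O06Rik, at 0.273, had an interval of -0.46 to 1.01, too wide to tell. The other 5 genes thus rose by more than the macrophage list's median. The criterion, however, asked that all 6 lie above the upper quartile, and the run was set from its own rise. Retnla and Gpnmb, picked above, rose by 0.80 and 0.68, as much as some of these genes. A larger number of macrophages therefore stays open for the run, including Tlr7 and Tlr8. Differences in sequence under the probes between parental strains remain open, since 100% of the 8 brighter genes were higher, as 1 better-matching haplotype could also give, and probe sequences were not used here. All mice are given as FVB, so this reading needs a second strain that the description above does not name. A translocation of this part of the X chromosome to the Y is known from another mouse strain, the Yaa mutation; whether these mice carry it, and whether the higher Tlr7 bears on other genes, was not tested.

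Among genes of the sex chromosomes, Xist differed by -0.11 ± 0.11 (SE) and Eif2s3y by -0.05 ± 0.06, both short of the limma threshold. Srsy, a multicopy gene of the Y chromosome, had 19 rows with changes of 0.76 to 1.30, of which 4 passed in limma; near-identical copies share probes, so these rows are not separate measurements. Whether this difference on the Y chromosome is linked to the run on the X was not tested. Of 742 measured genes of the X chromosome 16 were called, 11 of them higher.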
